A study of Homo sapiens with 8 samples.

How the data were processed

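RNA was measured in 8 samples of THP-1 cells, 2 in each of 4 groups: buffer control, TNFα, IL-6 and LPS. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with RNeasy columns, labelled with Cy3 using the Quick-Amp kit and hybridised to Agilent one-colour arrays, and the deposited intensity values were made by Agilent Feature Extraction 11.5.1.1, per the file headers, with background subtraction and detrending. The headers name the hg18 annotation; no genome was used here and no coordinates are given. The deposited flags (well above background, saturated, outlier) are Feature Extraction's own, per the file headers. A second deposited table holds the authors' log2 values; how they were made is not given in the sources used here. Set against the scanner values over 12104 genes with 1 probe, each column equalled log2 processed signal minus a constant, at least 12005 genes within 0.02. Its column medians were -2.97 and -2.98 for control, -2.90 and -3.04 for TNFα, -2.99 and -3.00 for IL-6, and -2.99 and -3.05 for LPS; its genes were not centred, and it served as an alternative.

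Each array held 15744 spots, of which 15208 were not controls. No spot was saturated. Of the genes that met the detection rule below, 18 were dropped because outlier flags left a value missing. Probe names were updated through a table of RefSeq accessions: 13523 probes matched by accession, 1107 by symbol and 216 by synonym, and 362 kept the name in the file. The processed signal was put on the log2 scale and each array's 75th percentile over non-control spots was subtracted. Of 13506 genes, 1320 had several probes, and the probe with the highest mean signal was used. A gene was tested if well above background on both arrays of at least 1 group, which kept 9194 genes and left out 4312. Among called genes with several detected probes, a probe of opposite sign occurred for 0 of 9 with TNFα, 0 of 2 with IL-6 and 6 of 48 with LPS. Probes may not separate near-identical gene copies, such as HCAR2 and HCAR3, the CCL3 and CCL4 copies, CXCL1 to CXCL3 and the metallothioneins.

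All 8 arrays were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 4 residual and 4.16 prior degrees of freedom, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. A gene not well above background on any array of a group has only a bound there: the bright group's mean was set against the mean, per array, of the higher of the lowest signal well above background and the probe's own. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, for 22 lists and 6 comparisons, adjusted over the 132 tests. Of 65 calls, 18 held with the estimated correlation. The p-value also rose where the estimate was negative: for the NF-κB list with TNFα (-0.031), camera gave 5.7e-30 and then 0.00025. A lost call alone therefore does not show correlated members. The alternative fry, which does not set a list against other genes, kept 60 of the 65 and added 16. The lists held 450 distinct genes, of which 376 were tested. On simulated data with 9194 genes and 50 changed per size, TNFα against control recovered 28% of changes of 1 on the log2 scale. It recovered 70% of 1.5, 96% of 2 and 98% of 3, with 6 false calls. LPS against control recovered 26%, 78%, 90% and 98%, with 12 false calls. The simulated noise was normal and independent between genes, with variances drawn from the fitted prior. It had no background floor and no dimmer LPS arrays, so these rates may not hold for the real arrays.

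The groups, comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. For each treatment against control, the rule took the 12 largest rises and 8 largest falls among called genes whose treated arrays both lay beyond both control arrays. For other comparisons it took the 5 largest in each direction. It added up to 4 members of each list with the smallest adjusted p, and TNF, IL1B, IL6, CXCL8, CCL20, NFKBIA, TNFAIP3, SOCS3, BCL3, IL10, CXCL10 and IFNB1 in every comparison. Other list members named beside a count were chosen after their values were seen.

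The alternatives were normexp background correction with offset 50, quantile and median scaling, no filter and a stricter filter on dim spots, the mean of a gene's probes, the authors' table, a fit of only the compared groups, the replicate number as a block, a variance trend, a fold threshold, fry for lists, and leaving out each array. A detection floor common to all arrays, robust priors, and leaving out the dimmer TNFα and LPS arrays were added after seeing the data. The labels do not say what a shared replicate number means, so whether the numbers pair samples was not settled. Some genes that met these rules are not reported here. With 2 arrays per group, regrouping the samples was not run.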

Results

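Transcript levels were measured in THP-1 cells, a human monocytic leukaemia line that takes on macrophage-like features when given the phorbol ester PMA. After 48 h of PMA and 6 h without it, the cells were exposed for 2 h to 10 ng/ml tumour necrosis factor (TNFα), 50 ng/ml IL-6, 100 ng/ml bacterial lipopolysaccharide (LPS) or buffer alone as the control. Each of the 4 groups had 2 samples, and each sample had its own one-colour Agilent array. The sample titles mark the 2 samples of a group with BR and a number. Nothing in the labels states that they came from separate cultures, so the limma p-values of genes measure the spread between these samples, which may be technical. The camera p-values at the preset correlation set a list's genes against other genes, so they do not measure that spread. The number of arrays limits the precision. Replicate arrays correlated across genes at r = 0.986 to 0.992, where genes are not independent replicates.

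The 75th percentile of the processed signal was 299 and 220.5 on the control arrays, 233 and 175 on the TNFα arrays, 225 and 208 on the IL-6 arrays, and 145 and 118 on the LPS arrays. Spots well above background made up 65.8% and 66.5% of the control arrays, 65.8% and 61.6% of the TNFα arrays, 65.6% and 64.9% of the IL-6 arrays, and 59.2% and 54.5% of the LPS arrays. The LPS arrays were thus the dimmest. All 8 arrays lay on 1 slide and were read in 1 scan, with each group on its own 2 adjacent positions, so slide position and group cannot be told apart. In a principal component analysis the first component held 64.6% of the variance and placed the LPS arrays at 58.8 and 65.6, against -35.8 to -8.04 for the other arrays.

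The series sets infection-mediated against systemic inflammation, and its design gives 3 comparisons with the control and 3 between treatments. Of 9194 genes tested with limma at an adjusted p below 0.05, TNFα changed 199, IL-6 changed 81 and LPS changed 1639. Values below are log2 fold changes ± standard error with 2 arrays per group. A gene not well above background in the dimmer group has only a lower bound, given as "at least".

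**Figure D1:**
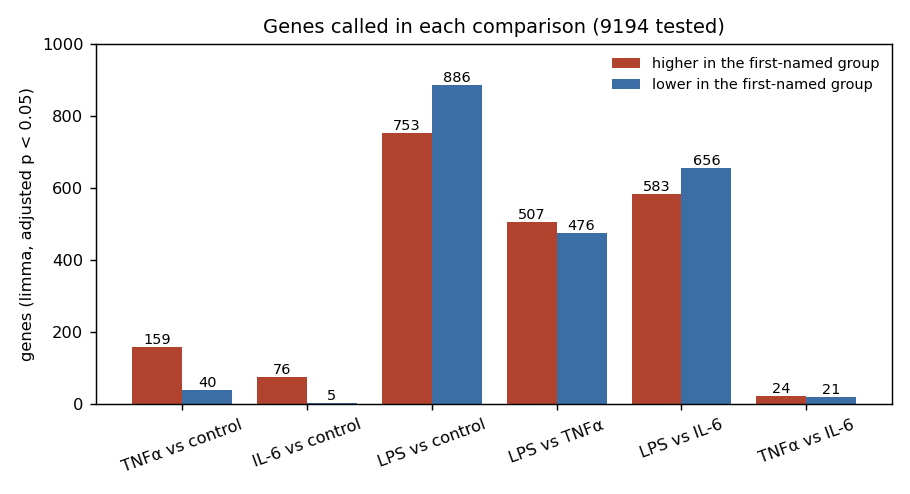
Number of genes (vertical axis) called higher or lower in the first-named group of each comparison (horizontal axis; limma, adjusted p below 0.05). LPS against control gave 753 higher and 886 lower genes, against 159 and 40 for TNFα and 76 and 5 for IL-6.

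The first comparison asked what TNFα changed within 2 h. TNFα raised chemokines, NF-κB pathway genes and the cytokines TNF and IL1B. CCL4, a chemokine that attracts monocytes and lymphocytes, rose by 5.53 ± 0.18 (46.2-fold; adjusted p = 4.8e-06), and the chemokines CCL20 and CXCL3 rose by 4.57 ± 0.17 and 4.50 ± 0.26. IL1B rose by 5.05 ± 0.29 and TNF itself by 4.38 ± 0.28. The hyaluronan-binding protein gene TNFAIP6 and the apoptosis inhibitor BIRC3 each rose by 5.29, with standard errors of 0.18 and 0.25. From control levels below background, the matricellular protein gene CCN2 rose at least 16.2-fold, the hydroxycarboxylic acid receptor HCAR3 at least 41.6-fold and the chemokine CCL8 at least 14.0-fold. RNF144B, an E3 ubiquitin ligase, rose by 4.52 ± 0.29. Among the largest falls were those of ID1, an inhibitor of helix-loop-helix transcription factors, by -2.95 ± 0.21, of the adenosine receptor ADORA3 by -2.85 ± 0.37, and of PDK4, a kinase that restrains pyruvate dehydrogenase, by -2.48 ± 0.22. The call for ADORA3 was lost under quantile normalization. The largest fitted rise was that of SHROOM3, an actin-binding protein gene, by 8.08 ± 0.64, with 1 of 2 control arrays above background.

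Of 18 tested NF-κB pathway genes and feedback inhibitors, 10 rose with TNFα over all genes and 17 when adjusted over the list alone. The inhibitor NFKBIA rose by 2.52 ± 0.21, the deubiquitinase TNFAIP3 by 2.97 ± 0.26, the adaptor TRAF1 by 3.57 ± 0.18 and the subunit gene NFKB1 by 2.13 ± 0.18, and the list stood above other genes (camera, adjusted p = 1.9e-28; adjusted p = 0.025 with an estimated correlation). Of 22 chemokines 11 rose, and 13 when adjusted over the list alone (camera, adjusted p = 4e-19; adjusted p = 0.056 with an estimated correlation). Of 22 immediate-early genes 5 rose and 1 fell, and 11 rose and 2 fell when adjusted over the list alone (adjusted p = 9e-08; adjusted p = 0.045 with an estimated correlation). The early-response gene IER3 and the nuclear receptor NR4A3 rose by 2.61 ± 0.20 and 2.29 ± 0.19. The member that fell, the transcription factor KLF4, was singled out after its values were seen (-1.24 ± 0.22). Its call was lost without control replicate 1 or 2 or TNFα replicate 1 or 2 (adjusted p of 0.18, 0.11, 0.080 and 0.11), under normexp (-0.35; 0.48), with no filter on dim spots (0.10), in a fit of the TNFα and control arrays alone (0.065), at the detection floor (0.079) and without the dimmer TNFα and LPS arrays (0.085). Of 16 inflammatory cytokines 3 rose and 1 fell, and 4 rose and 1 fell when adjusted over the list alone, with the list itself at adjusted p = 0.052. The fall, that of OSM, lost its call in each of the 8 fits without 1 array (adjusted p from 0.067 to 0.23), and so did the rise of EBI3 in all but that without TNFα replicate 2 (0.063 to 0.23). Both were also lost with no filter on dim spots (0.12 and 0.11) and in a fit of the TNFα and control arrays alone (0.14 and 0.16), OSM under median scaling (0.063) and without the dimmer TNFα and LPS arrays (0.093), and EBI3 in the authors' table (0.05005) and at the detection floor (0.079). The transcripts of IL6 (0.50 ± 0.23) and IFNB1 (1.07 ± 0.59) did not pass and were below background with and without TNFα.

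Among 22 IL-6/STAT3 response genes, SOCS3, BCL3 and BCL6 rose with TNFα by 2.18 ± 0.23, 2.17 ± 0.22 and 2.02 ± 0.20, and 7 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 0.00092; adjusted p = 0.14 with an estimated correlation). Of 19 survival and apoptosis regulators 3 rose, and 7 when adjusted over the list alone, among them BCL2A1 by 1.59 ± 0.19 (camera, adjusted p = 0.00018; adjusted p = 0.064 with an estimated correlation). Of 20 antigen presentation genes, CD83 and CD40, markers of activated antigen-presenting cells, rose by 3.09 ± 0.17 and 1.59 ± 0.18, and the same number, 2, when adjusted over the list alone (adjusted p = 0.006; adjusted p = 0.14 with an estimated correlation). The prostaglandin enzyme PTGS2 (cyclooxygenase) rose by 2.94 ± 0.22 and the receptor PTGER2 by 1.69 ± 0.20; 3 of 12 genes of that list rose, also when adjusted over the list alone (adjusted p = 0.0063; adjusted p = 0.11 with an estimated correlation), and its median was 0.07 above that of all genes but 0.03 below it (-0.03) under normexp background correction. ICAM1, the leukocyte adhesion molecule, rose by 2.98 ± 0.19 and SOD2, the mitochondrial superoxide dismutase, by 2.50 ± 0.23. Of 31 interferon-stimulated genes 3 rose, also when adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.29 with an estimated correlation); the member with the smallest p, IDO1, had no call under normexp or at the detection floor. Of the other members, GBP2 lost its call in each of the 8 fits without 1 array (adjusted p from 0.065 to 0.26), and GBP5 without control replicate 1 or 2, TNFα replicate 2 or IL-6 replicate 1 or 2 (0.22, 0.12, 0.13, 0.069 and 0.069). Both were also lost with no filter on dim spots (0.13 and 0.10), in a fit of the TNFα and control arrays alone (0.17 and 0.13) and without the dimmer TNFα and LPS arrays (0.063 and 0.14), and GBP2 in the authors' table (0.060) and at the detection floor (0.072).

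The 10 tested markers of other cell types had a median of -0.26 with TNFα (camera, adjusted p = 0.039; adjusted p = 0.30 with an estimated correlation), while with limma 0 of them passed and 1 had an unadjusted p below 0.05. Of the 22 lists 10 were called with TNFα, of which 2 held with an estimated correlation.

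The counts for TNFα were 159 higher and 40 lower, of which 181 changed at least 2-fold. Without control replicate 1, 98 genes passed, a fit of the TNFα and control arrays alone gave 101, and a fit with no filter on dim spots gave 115.

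The next comparison asked the same of IL-6. IL-6 raised chemokines, TNF and IL1B together with STAT3 response genes, and nearly all of its calls were rises. CCL4 rose by 4.73 ± 0.18 (26.6-fold; adjusted p = 3e-05), IL1B by 4.67 ± 0.29 and TNF by 3.96 ± 0.28. The neutrophil attractants CXCL2 and CXCL3 rose by 3.56 ± 0.26 and 3.54 ± 0.26, and CCL2, a monocyte attractant, by 3.29 ± 0.28. IL7R, the receptor chain for interleukin-7, rose by 3.52 ± 0.23. From control levels below background, CCL8 rose at least 14.4-fold and HCAR3 at least 13.6-fold. SOCS3, a feedback inhibitor of the IL-6 receptor, rose by 2.92 ± 0.23 (7.58-fold; adjusted p = 0.00062). The IL6 transcript did not pass (0.50 ± 0.23) and was below background on the IL-6 and the control arrays.

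Of 22 IL-6/STAT3 response genes 5 rose with IL-6, and 8 when adjusted over the list alone (camera, adjusted p = 7e-12; adjusted p = 0.047 with an estimated correlation). These were SOCS3, BCL3 (2.27 ± 0.22), HAMP, which encodes the iron hormone hepcidin (1.73 ± 0.19), BCL6 (1.62 ± 0.20) and the kinase PIM1, (1.28 ± 0.20). The call for PIM1 was lost without control replicate 1 or 2 or IL-6 replicate 1 or 2 (adjusted p of 0.20, 0.14, 0.18 and 0.25), with no filter on dim spots (0.11) and at the detection floor (0.069). The call for HAMP was lost without IL-6 replicate 1 (adjusted p = 0.054), and that for BCL6 without control replicate 1 or either IL-6 array (adjusted p of 0.077, 0.098 and 0.085). Of 22 chemokines 9 rose, and 11 when adjusted over the list alone (adjusted p = 4.5e-23; adjusted p = 0.045 with an estimated correlation). Of 18 NF-κB pathway genes 6 rose, and 9 when adjusted over the list alone, among them BIRC3 by 3.77 ± 0.25, TRAF1 by 2.12 ± 0.18 and NFKBIA by 2.10 ± 0.21 (adjusted p = 5.4e-15; adjusted p = 0.025 with an estimated correlation). Of 22 immediate-early genes 3 rose, and 9 rose and 1 fell when adjusted over the list alone, led by IER3 at 2.38 ± 0.20 (adjusted p = 1.3e-08; adjusted p = 0.045 with an estimated correlation), but 1 rose without IL-6 replicate 2. Of 16 inflammatory cytokines 3 rose, and 5 rose and 1 fell when adjusted over the list alone (adjusted p = 7.1e-05; adjusted p = 0.11 with an estimated correlation). ICAM1 rose by 2.04 ± 0.19 and CD83 by 1.72 ± 0.17, while CXCL10, an interferon-responsive chemokine, stood at 1.46 ± 0.26 and did not pass (adjusted p = 0.052). The 31 interferon-stimulated genes had a median of 0.19 with 2 rises, and 3 when adjusted over the list alone (adjusted p = 0.00092; adjusted p = 0.20 with an estimated correlation). These rises, of IDO1 and TRIM25, were lost without control replicate 1 (adjusted p of 0.21 and 0.081), IL-6 replicate 1 (0.11 and 0.054) or IL-6 replicate 2 (0.29 and 0.13), and that of TRIM25 also without control replicate 2 (0.076). The rise of IDO1 was also lost under normexp (0.24; adjusted p = 0.94), quantile normalization (0.096), with no filter on dim spots (0.11) and at the detection floor.

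SHROOM3 rose by 5.67 ± 0.64 with IL-6, a call lost without IL-6 replicate 1 or 2 (adjusted p of 0.053 and 0.069). Of 22 pattern recognition genes, 0 passed with limma and 6 had an unadjusted p below 0.05, all higher, and 1 rose when adjusted over the list alone, while the list stood above other genes (camera, adjusted p = 0.00097; adjusted p = 0.16 with an estimated correlation). Of the 22 lists 11 were called with IL-6, of which 4 held with an estimated correlation.

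The 5 genes that fell with IL-6 were TNFSF14 (-1.75), ID1 (-1.47), SKIDA1 (-1.40), HES1 (-1.28) and PEX11A (-1.21). PEX11A was above background on 1 of 2 IL-6 arrays. Each of these falls was lost without control replicate 1 (adjusted p from 0.081 to 0.30), IL-6 replicate 1 (0.13 to 0.29) or IL-6 replicate 2 (0.11 to 0.22), all but TNFSF14 without control replicate 2 (0.11 to 0.15), and PEX11A without either LPS array (0.075). With no filter on dim spots all 5 were lost (0.074 to 0.13). Under normexp SKIDA1 (-0.16; adjusted p = 0.94) and PEX11A (-0.015; 0.99) were not called, nor were HES1 and PEX11A under median scaling (0.056 and 0.069), PEX11A with a variance trend (0.34), or TNFSF14, ID1, HES1 and PEX11A at the detection floor (0.12, 0.062, 0.082 and 0.25). The number of IL-6 calls was 48 without control replicate 1, 42 without IL-6 replicate 1 and 35 without IL-6 replicate 2, but 128 in a fit of the IL-6 and control arrays alone and also 128 without the dimmer TNFα and LPS arrays. The share of calls that were higher was 93.8%, and 83.5% under normexp background correction.

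LPS against control asked for the response to a bacterial product. LPS raised interferon-stimulated genes, cytokines, chemokines and immediate-early genes, many from below background. The interferon gene IFNB1 rose at least 499-fold, the cytokine gene IL6 at least 935-fold, HCAR3 at least 1476-fold, CCL8 at least 744-fold and CH25H, an enzyme that makes an oxysterol, at least 234-fold. PTGS2 rose by 9.93 ± 0.22 (976-fold; adjusted p = 8.6e-08), CXCL10 by 8.80 ± 0.26 with 1 of 2 control arrays above background, TNF by 8.38 ± 0.28 and the nuclear receptor NR4A3 by 8.32 ± 0.19. SOCS3 rose by 7.14 ± 0.23, IL1B by 6.76 ± 0.29, TNFAIP3 by 4.93 ± 0.26, NFKBIA by 3.58 ± 0.21 and CXCL8, a neutrophil attractant, by 3.38 ± 0.23. IL10, an anti-inflammatory cytokine, stood at 0.56 ± 0.27 and did not pass (adjusted p = 0.20). Among the falls, PDK4 dropped at least 25.6-fold, the acid-sensing receptor GPR65 at least 12.8-fold, the ID1 relative ID3 at least 9.13-fold and the homeobox factor HHEX at least 9.08-fold, each to below background on both LPS arrays, and ID1 fell by 4.52 on the log2 scale (standard error 0.21).

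**Figure D2:**
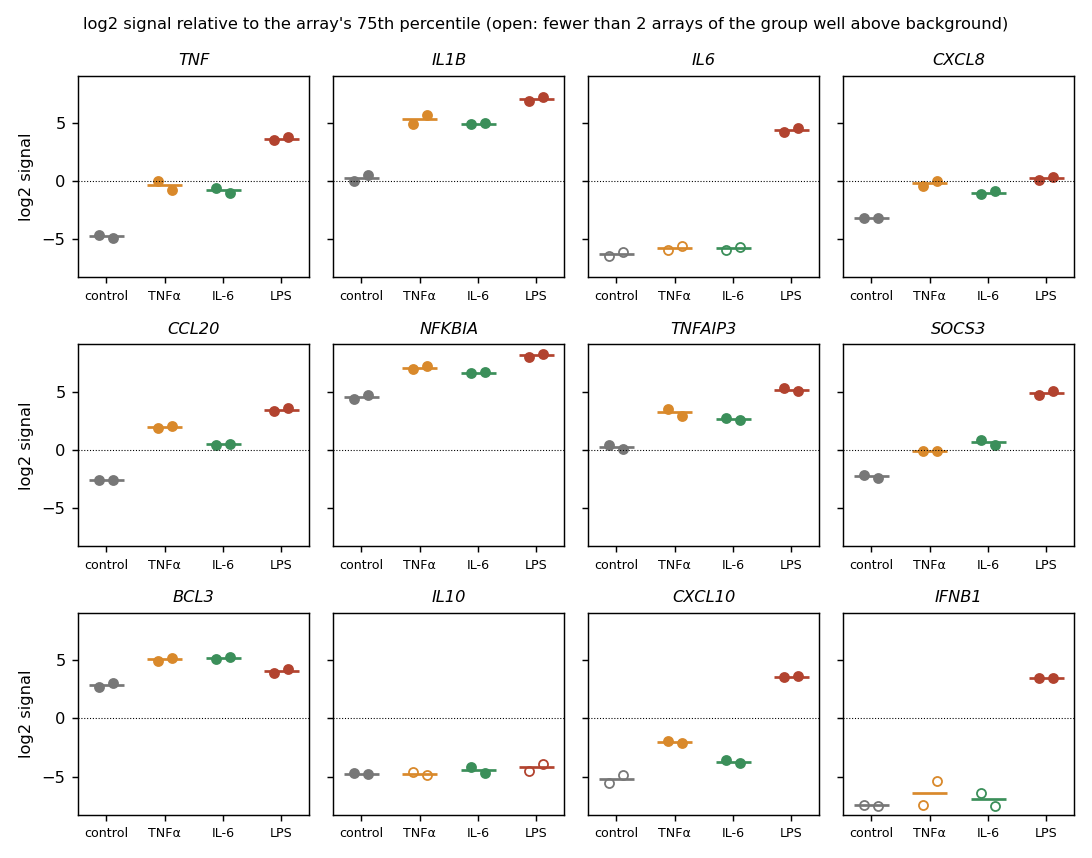
Log2 signal relative to the array's 75th percentile (vertical axis) of 12 genes fixed before the data were examined, in the 4 groups (horizontal axis). Each point is an array, each line the mean of 2 arrays, and open points mark groups with fewer than 2 arrays well above background. IL6 and IFNB1 were well above background only in the LPS group, and BCL3 was higher with TNFα (2.17) and IL-6 (2.27) than with LPS (1.16), as log2 fold changes against control.

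Of 31 interferon-stimulated genes 30 rose with LPS, also when adjusted over the list alone, with a median of 3.14 (camera, adjusted p = 7e-32; adjusted p = 0.028 with an estimated correlation). IFIT3 and OASL, antiviral effectors, rose by 8.17 ± 0.18 and 7.64 ± 0.18, the exonuclease ISG20 by 6.93 ± 0.18 and the guanylate-binding protein GBP5 by 5.38 ± 0.19. Of 22 immediate-early genes 19 rose and 1 fell, also when adjusted over the list alone (adjusted p = 9.7e-17; adjusted p = 0.025 with an estimated correlation): the phosphatase DUSP2 rose by 5.84 ± 0.20, FOSB at least 10.3-fold and EGR3 at least 21.7-fold, while FOS, named after its values were seen, fell (-2.29 ± 0.25). Of 18 NF-κB pathway genes 14 rose and 1 fell, and 15 and 1 when adjusted over the list alone, with TRAF1 at 7.002 ± 0.18 and BIRC3 at 6.53 ± 0.25 (adjusted p = 3.5e-12; adjusted p = 0.025 with an estimated correlation). BCL3, a nuclear IκB family member, rose by 1.16 ± 0.22, a call lost without control replicate 1 or LPS replicate 2 (adjusted p of 0.058 in both). Of 16 inflammatory cytokines 12 rose and 1 fell, and 13 and 1 when adjusted over the list alone, among them IL15 by 4.14 ± 0.20 (adjusted p = 6.2e-12; adjusted p = 0.045 with an estimated correlation). Of 22 chemokines 16 rose, and 17 when adjusted over the list alone, with CCL4 at 7.66 ± 0.18, CCL20 at 6.05 ± 0.17 and CCL3 at 5.67 ± 0.20 (adjusted p = 2.2e-17; adjusted p = 0.061 with an estimated correlation). The NF-κB pathway gene that fell, TRAF2, lost its call with no filter on dim spots (adjusted p = 0.051), without the dimmer TNFα and LPS arrays (0.14) and without control replicate 1 or 2, IL-6 replicate 1 or 2 or LPS replicate 1 or 2 (0.20, 0.087, 0.065, 0.065, 0.073 and 0.19). The cytokine that fell, OSM, lost it without control replicate 1 or 2 or LPS replicate 1 (0.071, 0.071 and 0.073).

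Smaller or mixed lists followed. An adjusted p paired with one at an estimated correlation is the camera value of the list, not of a gene named before it. Of 16 anti-inflammatory mediators 9 rose and 1 fell with LPS, and 11 and 1 when adjusted over the list alone, with the checkpoint ligand CD274 up at least 18.2-fold and the receptor antagonist IL1RN by 2.72 ± 0.18 (camera, adjusted p = 1.2e-06; adjusted p = 0.10 with an estimated correlation). Of 16 coagulation and protease genes 9 rose and 1 fell, also when adjusted over the list alone. The protease MMP12 rose at least 24.4-fold and the coagulation inhibitor TFPI2 at least 36.9-fold, while thrombomodulin, THBD, fell (-1.53 ± 0.17). The list as a whole stood above other genes (camera, adjusted p = 0.00013, and adjusted p = 0.068 with an estimated correlation). Of 19 survival regulators 9 rose and 2 fell, also when adjusted over the list alone, with BCL2A1 at 3.68 ± 0.19 (adjusted p = 0.002; adjusted p = 0.092 with an estimated correlation). Of 22 IL-6/STAT3 response genes 11 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.0025; adjusted p = 0.16 with an estimated correlation), but 5 rose without control replicate 1 and 6 without LPS replicate 2. Of 19 antioxidant and metallothionein genes 6 rose and 1 fell, and 8 and 1 when adjusted over the list alone, with SOD2 at 4.11 ± 0.23 and the metallothionein MT2A at 3.15 ± 0.29 (adjusted p = 0.021; adjusted p = 0.14 with an estimated correlation). Of 20 antigen presentation genes 4 rose, and 5 when adjusted over the list alone, with CD83 at 4.80 ± 0.17 (adjusted p = 0.00097; adjusted p = 0.12 with an estimated correlation). The prostaglandin list had 4 rises and 1 fall among 12 genes, also when adjusted over the list alone, including the phospholipase PLA2G4A at 1.93 ± 0.21 (adjusted p = 0.018; adjusted p = 0.14 with an estimated correlation). TNF and IL-6 receptors and kinases had 5 rises among 12, also when adjusted over the list alone, such as the kinase RIPK2 at 3.31 ± 0.19 (adjusted p = 0.021; adjusted p = 0.14 with an estimated correlation), and 3 without control replicate 1, control replicate 2 or LPS replicate 1. Adhesion molecules had 4 rises among 15, also when adjusted over the list alone, such as ICAM1 at 3.30 ± 0.19 (adjusted p = 0.0063; adjusted p = 0.11 with an estimated correlation), with a median 0.29 above that of all genes that lay below it (-0.07) under normexp. Several single falls in these lists were fragile. LILRB1, the anti-inflammatory mediator that fell, was called higher under normexp (0.59; adjusted p = 0.012), and its fall was lost with a variance trend (0.079), at the detection floor and without control replicate 2 or LPS replicate 1 (0.15 in both). HMOX1, the antioxidant gene, lost its fall in the same fits without 1 array (0.078 and 0.060). Of the survival regulators, BAK1 lost its fall without control replicate 1, IL-6 replicate 1 or 2 or LPS replicate 2 (0.19, 0.057, 0.057 and 0.18), at the detection floor (0.061) and without the dimmer TNFα and LPS arrays (0.14). BCL2L1 lost it without control replicate 2 or LPS replicate 1 (0.082 and 0.067), with the mean of its probes (0.05; adjusted p = 0.92) and under normexp, where it turned positive (0.43; adjusted p = 0.055). The prostaglandin gene PTGS1 lost its fall under normexp (-0.01; adjusted p = 0.96), with no filter on dim spots (0.051), at the detection floor (0.062) and without the dimmer TNFα and LPS arrays (0.10). It was also lost without control replicate 1, IL-6 replicate 1 or 2 or LPS replicate 1 or 2 (0.22, 0.057, 0.057, 0.098 and 0.16).

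Of 22 pattern recognition genes 4 rose and 4 fell with LPS, also when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.55). The DNA sensor AIM2 rose by 3.40 ± 0.18 and the receptor TLR1 fell (-2.05 ± 0.26), while the falls of TLR5 and TLR6 turned positive under normexp (0.48 and 0.24), and that of TLR5 was lost at the detection floor (adjusted p = 0.16). Of 17 heat shock and unfolded protein response genes 1 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.90): the transcription factor XBP1 rose by 3.08 ± 0.27 and the stress factor DDIT3 fell (-1.83 ± 0.23). The fall of DNAJB1 was lost without control replicate 1 or 2 or LPS replicate 2 (adjusted p of 0.088, 0.058 and 0.092) and without the dimmer TNFα and LPS arrays (0.085). The glycolysis and hypoxia list had 3 rises and 1 fall among 16 genes, also when adjusted over the list alone (camera, adjusted p = 0.19). PFKFB3, an activator of glycolysis, stood at 1.88 ± 0.23. The fall, of NDRG1, was a called rise under normexp (0.63; adjusted p = 0.011), and was lost at the detection floor and without LPS replicate 1 (0.053). The cholesterol list had 3 rises among 18, with 3 rises and 1 fall when adjusted over the list alone (adjusted p = 0.46), but 1 rise without LPS replicate 2. The cell cycle list had 1 rise and 2 falls among 20, also when adjusted over the list alone (adjusted p = 0.32). All 3 of these calls were lost without control replicate 1 (adjusted p of 0.097 for CCNB1, 0.14 for AURKA and 0.15 for MKI67) or LPS replicate 2 (0.078, 0.093 and 0.19). Those of CCNB1 and AURKA were also lost without LPS replicate 1 (0.065 and 0.072) and that of MKI67 without control replicate 2 (0.067). Under normexp CCNB1 was not called (0.065) and MKI67 turned positive (0.18), and at the detection floor MKI67 was not called (0.085). All 3 calls were lost without the dimmer TNFα and LPS arrays (0.052, 0.065 and 0.14). Macrophage markers had 1 fall among 18 but 0 when adjusted over the list alone (adjusted p = 0.17). The fall, of FCGR3A, was lost without control replicate 1 or 2 or LPS replicate 1 or 2 (0.11, 0.19, 0.12 and 0.15), under median scaling (0.061), with no filter on dim spots (0.053), in a fit of the LPS and control arrays alone (0.051) and without the dimmer TNFα and LPS arrays (0.14). Of 15 reference genes B2M rose, also when adjusted over the list alone, a call lost without control replicate 1 or LPS replicate 2 (adjusted p of 0.069 and 0.067) or without the dimmer TNFα and LPS arrays (0.052), and the list stood at adjusted p = 0.11. Of 10 markers of other cell types FCGR3B and PDGFRB were lower, also when adjusted over the list alone (camera, adjusted p = 0.37); both changed sign under normexp, at 0.48 and 0.34. FCGR3B was not called without control replicate 2 or LPS replicate 1 (adjusted p of 0.060 and 0.068), nor PDGFRB without control replicate 2, LPS replicate 1 or LPS replicate 2 (0.15, 0.090 and 0.11), and neither at the detection floor (0.13 and 0.0504). Of the 22 lists 14 were called with LPS, of which 4 held with an estimated correlation.

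Beside these groups, the LPS arrays were the dimmest, and 228 of the 1639 genes called with LPS were below background on both LPS arrays. Of the 1639 genes, 1271 were also called under normexp, and only 1115 of these kept their direction. The calls split into 753 higher and 886 lower, 45.9% higher, against 4095 calls with 81.5% higher under normexp, which moved the median of all genes to 0.21; a fit without the filter on dim spots gave 2882 calls, and 1007 and 1041 genes passed without control replicate 1 and LPS replicate 2.

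**Figure D3:**
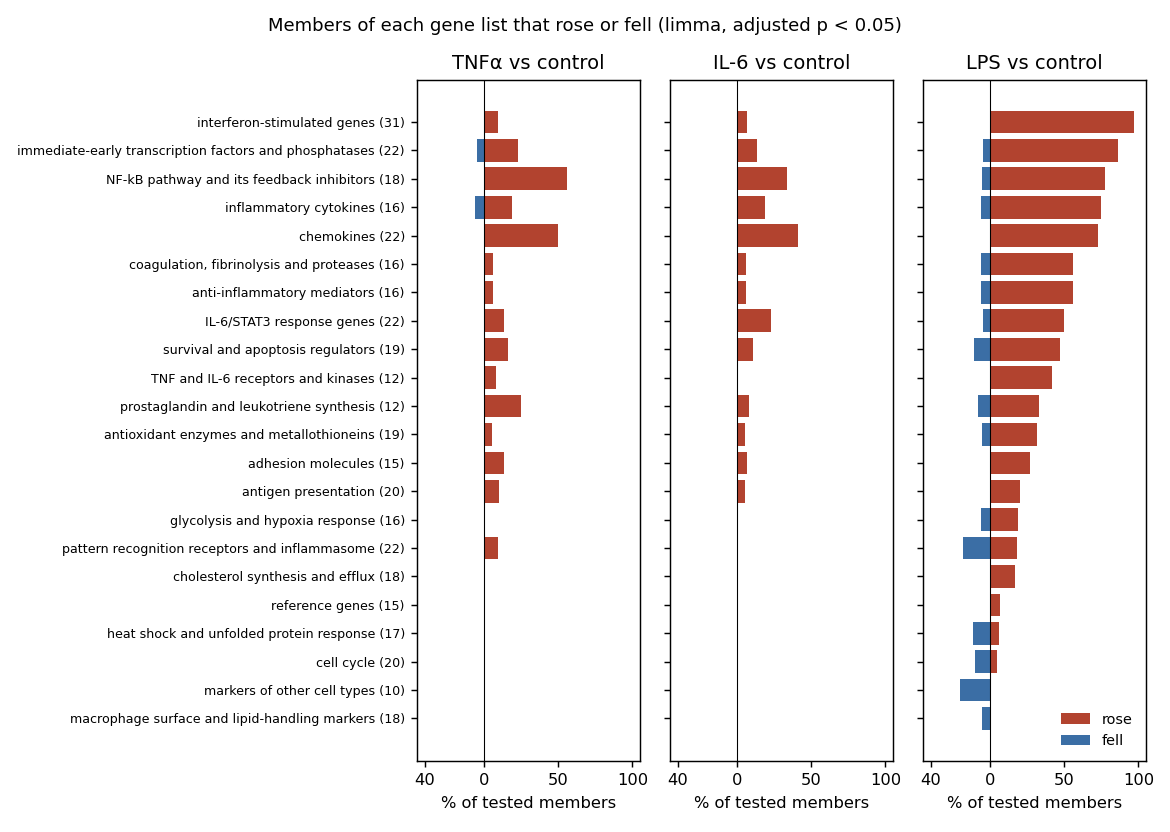
Percent of each list's tested members (horizontal axis, rises to the right and falls to the left) that changed against control with TNFα, IL-6 and LPS, for 22 lists (vertical axis, tested members in brackets). With LPS, 30 of 31 interferon-stimulated genes rose.

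LPS against TNFα tested where the bacterial product and this cytokine differed directly. Of 31 interferon-stimulated genes 30 were higher with LPS, also when adjusted over the list alone (camera, adjusted p = 4.2e-40; adjusted p = 0.025 with an estimated correlation), with OASL at 7.29 ± 0.18 and IFIT3, above background on 1 of 2 TNFα arrays, at 8.56 ± 0.18. IL6 was at least 802-fold higher with LPS, ANGPTL4, an inhibitor of lipoprotein lipase, at least 898-fold and IFNB1 at least 428-fold, each below background on the TNFα arrays. CXCL10, SOCS3 and TNF were higher by 5.63 ± 0.26, 4.96 ± 0.23 and 3.997 ± 0.28, and PTGS2 by 6.99 ± 0.22. IL1B and CCL20 differed less, by 1.71 ± 0.29 and 1.47 ± 0.17, and CXCL8 did not pass (0.43 ± 0.23; adjusted p = 0.32). The call for IL1B was lost without LPS replicate 2 (adjusted p = 0.054). Lower with LPS were TIGD2, a transposase-derived gene (-2.82 ± 0.36), the transcription factor KLF15, at least 2.50-fold, and the kinase PDIK1L, at least 4.74-fold; the calls for KLF15 and PDIK1L were lost under normexp.

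Of 22 immediate-early genes 17 were higher and 1 lower with LPS than with TNFα, and 18 and 1 when adjusted over the list alone (camera, adjusted p = 2.1e-16; adjusted p = 0.025 with an estimated correlation). The lower gene, FOS, lost its call without TNFα replicate 1, LPS replicate 1 or LPS replicate 2 (adjusted p of 0.063, 0.051 and 0.079). Of 16 inflammatory cytokines 11 were higher, also when adjusted over the list alone (adjusted p = 1.1e-13; adjusted p = 0.043 with an estimated correlation). Of 22 chemokines 11 were higher, also when adjusted over the list alone, among them CCL5 by 3.89 ± 0.21 (adjusted p = 3.5e-12; adjusted p = 0.091 with an estimated correlation). Of 18 NF-κB pathway genes 9 were higher and 3 lower, and 13 and 3 when adjusted over the list alone (adjusted p = 8.4e-05; adjusted p = 0.061 with an estimated correlation), but 1 was lower without TNFα replicate 2 or LPS replicate 1. BCL3 was lower with LPS (-1.003 ± 0.22), a call lost without TNFα replicate 2 or LPS replicate 1 (adjusted p of 0.097 and 0.12), with no filter on dim spots (0.058) and without the dimmer TNFα and LPS arrays (0.094). The comparison gave 983 genes, 507 higher and 476 lower (51.6% higher, and 66.8% under normexp, which put the median of all genes at 0.15), and 600 without LPS replicate 2.

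LPS against IL-6 gave a similar list of leading genes. IFNB1 was at least 469-fold and IL6 at least 879-fold higher with LPS, ANGPTL4 was higher by 9.33 ± 0.41, IFIT3 by 8.08 ± 0.18, PTGS2 by 7.94 ± 0.22, CXCL10 by 7.33 ± 0.26, TNF by 4.43 ± 0.28 and SOCS3 by 4.22 ± 0.23. Lower with LPS were NFE2, a transcription factor of blood cell lineages (-5.96 ± 0.45, with 1 of 2 LPS arrays above background), the transcriptional repressor GFI1 (-3.17 ± 0.22), GPR65, at least 12.7-fold, PDK4, at least 10.99-fold, and HAMP (-2.01 ± 0.19). Of 31 interferon-stimulated genes 28 were higher, and 30 when adjusted over the list alone (camera, adjusted p = 4.6e-36; adjusted p = 0.025 with an estimated correlation). Of 18 NF-κB pathway genes 13 were higher and 1 lower, and 13 and 2 when adjusted over the list alone (adjusted p = 2.1e-09; adjusted p = 0.029 with an estimated correlation). The lower one was BCL3 (-1.10 ± 0.22), a call lost without either IL-6 array or LPS replicate 1 (adjusted p of 0.051, 0.091 and 0.073), and 2 genes were lower without TNFα replicate 1 or 2. Of 22 IL-6/STAT3 response genes 6 were higher and 7 lower, and 7 and 9 when adjusted over the list alone, and the list did not pass (adjusted p = 0.95); 3 were lower without IL-6 replicate 1, IL-6 replicate 2 or LPS replicate 1. The comparison gave 1239 genes, 583 higher and 656 lower (47.1% higher), against 2678 genes and 80.02% higher under normexp, where the median of all genes was 0.18. Without IL-6 replicate 1, IL-6 replicate 2 or LPS replicate 2, 720, 693 and 823 genes passed.

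TNFα against IL-6 tested the difference between the cytokines. NF-κB pathway genes were higher with TNFα as a list: 3 of 18 passed, and 9 when adjusted over the list alone (camera, adjusted p = 9.1e-16; adjusted p = 0.025 with an estimated correlation) with TRAF1 at 1.45 ± 0.18. CCN2 was higher with TNFα by 2.49 ± 0.24, TNFAIP6 by 2.13 ± 0.18, and CCL20 by 1.52 ± 0.17. Higher with IL-6 were NFE2 (-4.0005 ± 0.45 for TNFα against IL-6), IL7R (-2.85 ± 0.23) and HAMP (-2.09 ± 0.19). Of 22 IL-6/STAT3 response genes HAMP passed, and 6 were lower with TNFα when adjusted over the list alone (adjusted p = 0.0078; adjusted p = 0.20 with an estimated correlation); SOCS3 did not pass (-0.74 ± 0.23; adjusted p = 0.33). Of 22 chemokines 2 were higher with TNFα, and 7 higher and 2 lower when adjusted over the list alone (adjusted p = 0.0014; adjusted p = 0.26 with an estimated correlation). TNF (0.43 ± 0.28) and IL1B (0.38 ± 0.29) did not pass. Without LPS replicate 1 or 2, 1 NF-κB pathway gene and 1 chemokine were called, and without TNFα replicate 2, IL-6 replicate 1 or IL-6 replicate 2 all of these NF-κB pathway genes and chemokines lost their calls. Without TNFα replicate 1, 1 chemokine was called. The call for HAMP was lost without IL-6 replicate 1 or 2 (adjusted p of 0.067 and 0.093).

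This comparison gave 45 genes, 24 higher and 21 lower with TNFα (53.3% higher, and 64.6% of 79 under normexp), and it rested on single arrays. It gave 15 genes without TNFα replicate 2, 6 without IL-6 replicate 1 and 27 without either LPS array, and with limma 0 without IL-6 replicate 2, where 445 genes had an unadjusted p below 0.05; all genes named here lost their call without IL-6 replicate 2, at an adjusted p of 0.093 for CCN2, TNFAIP6, IL7R and HAMP, 0.20 for CCL20 and NFE2, and 0.23 for TRAF1. Without TNFα replicate 2 the adjusted p was 0.064 for CCL20 and TRAF1 and 0.052 for NFE2, and without IL-6 replicate 1 it was 0.099 for CCL20 and TRAF1, 0.098 for NFE2 and 0.067 for HAMP. With no filter on dim spots CCN2 (0.057), CCL20, TRAF1 and NFE2 (0.086 each) lost their calls.

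The responses overlapped. Of the 199 genes called with TNFα, 169 changed the same way with LPS (143 higher, 26 lower) and 6 the opposite way; independent lists of these sizes would share 13.0 higher and 3.85 lower genes. Of the 81 genes called with IL-6, 60 changed the same way with TNFα (55 higher, 5 lower; 1.31 and 0.022 for independent lists) and 69 with LPS (65 higher, 4 lower; 6.22 and 0.48). A set of 55 genes rose with all 3 treatments, which included CCL4, CCL20, IL1B, TNF, NFKBIA, TNFAIP3, SOCS3 and BCL3. Fold changes across the 9194 genes correlated at r = 0.66 for TNFα and IL-6 (Spearman 0.52), 0.63 for TNFα and LPS (0.56) and 0.54 for IL-6 and LPS (0.49), across genes, which are not independent replicates. Unchanged groups simulated against the shared control arrays, with each gene's noise drawn independently, gave r = 0.50 (100 simulations). The covariances were 0.12, 0.30 and 0.21 against a simulated 0.036 for each pair. The same simulations gave on average 0 genes called with both TNFα and IL-6, 0 with both TNFα and LPS and 0.01 with both IL-6 and LPS (limma). No split of the 2 control arrays leaves 2 in each part, so part of the excess over independent lists may come from the shared controls.

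Of the 1464 genes called with LPS and not with TNFα, 797 differed in the direct test, as did 1047 of the 1568 called with LPS and not with IL-6. Of the 169 genes shared by TNFα and LPS, 91 changed more with LPS and 4 more with TNFα, and of the 69 shared by IL-6 and LPS, 52 changed more with LPS and 3 more with IL-6. Without control replicate 1 the overlap of TNFα and LPS was 89 genes, with no filter on dim spots 108, and with only the compared groups in each fit 94. Without control replicate 1, IL-6 replicate 1 and IL-6 replicate 2, the overlap of IL-6 with TNFα was 39, 34 and 30 genes and that with LPS 43, 39 and 33.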

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

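The detection floor, the robust priors and the omission of the dimmer TNFα and LPS arrays were chosen only after the results were seen. Median scaling and, for genes with 1 probe, the authors' table differed from the main values by little more than a constant per array. They were therefore weak tests of the processing. The number of called genes stayed within 1.5 times under quantile and median scaling, the authors' table, the mean of a gene's probes, robust priors, the detection floor and a 2-fold threshold. For the rest the cause was not tested. Under normexp it was 4095 for LPS, 2678 for LPS against IL-6 and 79 for TNFα against IL-6. With no filter on dim spots it was 115 for TNFα, 2882 for LPS and 5 for TNFα against IL-6, and the overlap of TNFα and LPS was 108. With only the compared groups it was 101 for TNFα, 128 for IL-6 and 86 for TNFα against IL-6, and that overlap was 94. For TNFα against IL-6 the stricter filter gave 69 and a variance trend 77. Without the dimmer TNFα and LPS arrays it was 128 for IL-6 and 69 for TNFα against IL-6.

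Leaving out 1 array gave 98 to 179 genes for TNFα, 35 to 92 for IL-6, 1007 to 1807 for LPS, 600 to 921 for LPS against TNFα, 693 to 1378 for LPS against IL-6 and, with limma, 0 to 51 for TNFα against IL-6, where the fit with 0 had 445 genes at an unadjusted p below 0.05. The lone array of a group was then assumed to vary like the others. The overlap was 30 to 64 for TNFα and IL-6, 89 to 151 for TNFα and LPS, and 33 to 78 for IL-6 and LPS.

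With the replicate number as a block, the counts were 241, 103 and 2183 against control, 1360, 1650 and 72 between treatments, and the overlaps 75, 213 and 87. Same-numbered arrays deviated together at r from 0.057 to 0.63 across genes, which did not settle the pairing. No slide or scan block was run, since all arrays shared both.

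Of 365 called values of genes named by the fixed rule, 322 kept their call under normexp and 12 changed sign. With TNFα these were CNTNAP2 at 0.088 and DSCAM at 0.086. With LPS they were FCGR3B at 0.48, MKI67 at 0.18, NDRG1 at 0.63, PDGFRB at 0.34 and TLR5 at 0.48. Against TNFα they were MLH3 at 0.25, NDRG1 at 0.43 and SEMA6D at 0.082, and against IL-6 NDRG1 at 0.50 and TLR5 at 0.31. Among list members named outside the rule, the LPS falls of LILRB1, BCL2L1 and TLR6 also turned positive. Dim spots limit the LPS falls and also the LPS rises of weakly expressed genes. After scaling, 4243 spots never above background read 1.05 higher (log2) on LPS than on control arrays, and 0.76 higher under normexp. With no filter on dim spots, LPS gave 2118 higher and 764 lower genes.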

Other observations

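The families with their tests, and the tests of explanations below, that at matched signal level among them, were chosen after the results were seen. The exceptions were the test of the background or scaling choice on the family's median, that of a fault of 1 LPS array and that of cross-hybridisation. The limma comparisons between groups were planned, while KLF4 and SGK1 were picked after their values were seen. Genes called in opposite directions with TNFα and LPS included KLF4 and SGK1. The transcription factor KLF4 stood at -1.24 with TNFα and 1.24 with LPS (LPS against TNFα, limma, adjusted p = 0.00022); its TNFα call was lost under normexp (-0.35, adjusted p = 0.48), with no filter on dim spots (0.10), in a fit of those groups alone (0.065), at the detection floor (0.079), without the dimmer TNFα and LPS arrays (0.085) and without control replicate 1 or 2 or TNFα replicate 1 or 2 (0.18, 0.11, 0.080 and 0.11). The kinase SGK1 went the other way, at 1.27 and -1.01 (0.00021); its TNFα call was lost with no filter on dim spots (adjusted p = 0.069), in a fit of those groups alone (0.086), without the dimmer arrays (0.063) and without control replicate 1 or TNFα replicate 2 (0.15 and 0.085), and its LPS call without control replicate 2 or LPS replicate 1 (0.076 and 0.064). The difference between LPS and TNFα kept its call for both genes in every alternative and every fit without 1 array that tested the gene. Both genes were picked for opposite calls against the same controls, which makes such a difference likely. It therefore does not bear on whether TNFα and LPS moved them in opposite directions from control.

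Zinc finger genes named ZNF and a number were lower with LPS in 134 of 308 cases (43.5%), against 8.46% of 8886 other genes (Fisher's exact test, 1 of 24 tests of 8 families, adjusted p = 5.4e-56). Genes are not independent replicates, so neither this p-value nor the odds ratio intervals below measure the spread between samples. With LPS 4 of these genes were higher, and 2 were lower with TNFα and 0 with IL-6 (limma). Their median lay 0.71 below that of all genes (-0.71), but at 0.0075 under normexp, where 52 were lower (16.9%, against 7.92% of other genes) and 112 higher (36.4%, against 36.3%), so the choice of background correction may account for part of the shift. At matched signal level the lowest odds ratio of being lower over those settings, that under normexp, was 6.41 (95% interval 4.28 to 9.60). This argues against background correction or scaling as the whole cause. Under normexp, however, the 220 ZNF genes with lower control levels had a median of 0.39, against 0.51 for other such genes. With the main processing these medians were -0.86 and -0.0063. The 88 ZNF genes with higher control levels stood at -0.43 under normexp, against -0.051. Among genes well above background on all 8 arrays, with the main processing, the odds ratio was 7.17 (5.22 to 9.84), which argues against dim arrays as the whole cause. Both LPS arrays showed the lower ZNF median (-0.75 and -0.70), which argues against a fault of 1 array. The exact slide position cannot be told apart from LPS, as 0 positions were shared by groups. The TNFα arrays shared slide column 2 with the LPS arrays (-0.10 and -0.05). The IL-6 arrays shared slide rows 3 and 4 with them (-0.036 and -0.13). These values argue against an effect of that column alone or of those rows alone. An LPS response of these genes stays open as a hypothesis.

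Many genes raised by IL-6 were also raised by TNFα and LPS. An admixture of LPS-treated RNA was set at the median share, 1.31%. Of 107 genes raised at least 16-fold by LPS, 48.6% lay over 3 standard errors from the IL-6 level at that share. Of these, 33 lay above the level and 19 below it, which argues against an admixture of that share as the whole source. Genes above the level may also respond to IL-6, so a smaller admixture as a contributor cannot be excluded. The covariance of the IL-6 and TNFα changes lay 68.8 simulated standard deviations above that from the shared controls. The simulations drew each gene's noise independently, while same-numbered control and TNFα arrays deviated together across genes (r = 0.63). This distance therefore cannot decide whether the shared controls are the whole cause. For TNFα-treated RNA, 21.9% of 73 genes lay over 3 standard errors from the level at the median share of 31.5%. The bound of 25% was set after the results were seen, so lying below it decides nothing. A single share left these 16 genes unaccounted for, and 15 of them lay above its level. Of these, 4 (CCL2, SOCS3, BCL3 and CCL8) needed a share over 100%, though none of the 4 differed between TNFα and IL-6 in limma (lowest adjusted p 0.33). Of the 55 genes raised by both, 0 were higher with IL-6 and 11 with TNFα in the direct test. An admixture of TNFα-treated RNA thus cannot be told apart from a response to IL-6 as the source of the shared rises. It could not supply the rises of IL7R and HAMP, which were lower with TNFα than with IL-6 (-2.85 and -2.09, calls lost without IL-6 replicate 2, adjusted p = 0.093, and for HAMP without IL-6 replicate 1, 0.067); a trace of another stimulus in the IL-6, or TNF made by the cells, may also contribute and was not tested.

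SHROOM3 rose in all 3 treatments, from -7.37 and -5.02 on the control arrays to 2.87 and 3.09 with LPS. Its 8 neighbouring spots had a median LPS change of -0.0261, which argues against light spilling over. Cross-hybridisation may still play a part: 0 of 15207 other probes shared 15 bases with its probe, but transcripts off the array were not searched, so this cannot be told apart from a rise of SHROOM3 itself.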
